A study of Anser cygnoides with 11 samples.

How the data were processed

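RNA sequencing of kidney was compared between 5 goslings with visceral gout and 6 healthy goslings. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected, and paired-end libraries were sequenced on an Illumina instrument. The labels also hold a treatment text on lowering oxygen in water tanks and a mention of adipose tissue, neither of which fits kidneys of goslings; both were left unused. Per the submitters' processing notes, HISAT and StringTie were used, with no version; the genome build is not given in the sources used here. The deposited FPKM values, fragment numbers scaled to transcript length and to the mapped fragments of the library, were made by the authors, and 1 column was matched to each gosling by its title. FPKM is scaled within a library, so a rise of abundant transcripts lowers the values of all others.

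Ratios of low values between libraries were examined for steps that single fragments would leave. In the 55 pairs of libraries at most 2.09% of rows shared a step, so no fragment counts were recovered, no count model was used and depth is unknown; no interval for counting error can be given. The labels describe the goslings as separate animals, and their sex, age and batch are not given. Differences between the groups in these could therefore not be examined.

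Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (linear model on group, empirical Bayes with a trend, two-sided), and tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Rows with at least 1 FPKM in at least 5 of the 11 libraries were kept: 12252 of 19275, of which 9283 had a gene symbol. A LOC number was given for 5896 rows and no name for 1087. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and a second count asked for an absolute log2 fold change of at least 1. Fold changes on this scale understate changes of rows near the pseudocount. Single values were tested with exact two-sided permutation tests over the 462 splits of the goslings.

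Before the data were examined, 38 gene lists with 1261 symbols were fixed for kidney segments, urate handling, injury, inflammation, other cell types, metabolism and RNA quality, of which 855 symbols were in the table and 767 tested. A symbol with several rows was represented by the most abundant. Lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the 37 lists with members. Named genes were the 12 largest rises and 12 largest falls with a symbol, a mean of at least 5 FPKM in the higher group and no overlap of the groups, up to 4 passing members of each list or the member with the smallest p where none passed, and 15 genes named in advance. The limits were met by 21 higher and 185 lower rows, and FKBP5 holds 2 of the 12 rises. Results of 2 named genes are not reported here; counts include them.

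The steps were tested on simulated data made from the 12252 tested rows of gout against control. In 5 simulations limma recovered 19.2% of 2-fold and 75.2% of 4-fold changes with 5.68% false calls. Rows of low abundance held no planted change. At unadjusted p under 0.05 camera found 5 of 5 changed lists and called 2 of 250 unchanged lists. The simulated rows varied independently of each other, so correlation between members of a list was not covered. The error rate of 2 of 250 may therefore not hold for the real lists. The alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter at 5 FPKM, quantile normalization, upper quartile scaling, the TPM scale, robust empirical Bayes, array weights, the label number as a block, each gosling left out, an exact rank-sum test, and for lists fry, the estimated correlation and summed rows. Renamed LOC numbers, the myeloid protein 1 gene as a covariate, quantile normalization without gout replicate 1 or with an estimated correlation, exact tests of list means over goslings and pathway enrichment were chosen after the data were seen. Gene neighbours were read from the order of genes by chromosome and start position in the RefSeq annotation of the Taihu goose genome assembly. Distances in bases were not used.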

Results

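Messenger RNA abundance was measured in kidney tissue of 11 goslings of the swan goose (Anser cygnoides), 5 with visceral gout and 6 healthy. Visceral gout is the deposition of urate on internal organs, and the kidney is the organ through which birds excrete most urate. The deposited table gave 1 FPKM column per gosling over 19275 rows, of which 12252 reached 1 FPKM in at least 5 libraries and were tested. The table holds no read counts, so sequencing depth is unknown. FPKM column totals ranged from 229465 to 399990 in gout and from 306484 to 390546 in control libraries (exact two-sided permutation p = 0.411).

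The libraries of the groups differed in composition. The 10 most abundant rows took 27.5% ± 1.65 of all FPKM in gout (SD, n = 5) and 21.2% ± 1.37 in control kidneys (SD, n = 6), with exact two-sided permutation p = 0.00216, the smallest that the splits of the goslings allow. Rows with at least 1 FPKM numbered 11284 ± 557 in gout and 12124 ± 249 in control libraries (SD, n = 5 and 6, exact two-sided permutation p = 0.00433). Pearson correlations of log2 values lay between 0.828 and 0.927 within gout and between 0.883 and 0.934 within control.

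**Figure D1:**
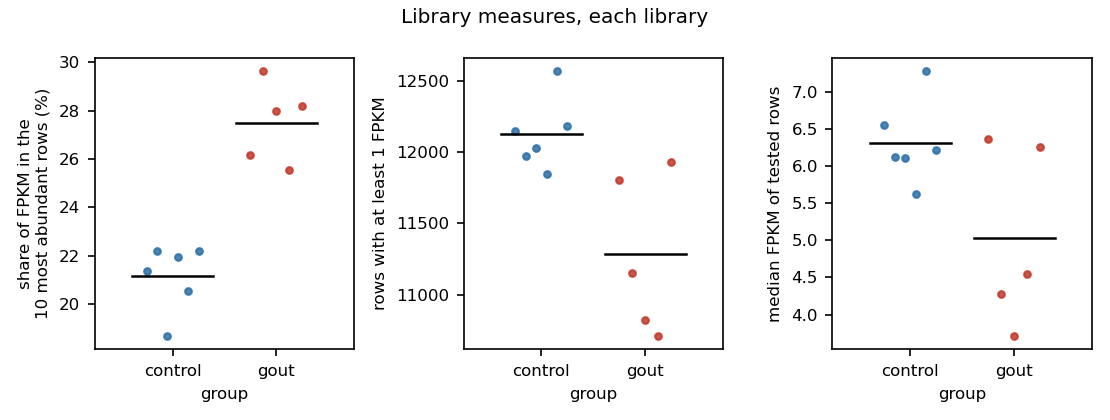
Library measures for each gosling: the percent of FPKM in the 10 most abundant rows, the number of rows with at least 1 FPKM and the median FPKM of tested rows, by group. Points are libraries and lines are group means; the share in the 10 most abundant rows was 27.5% in gout and 21.2% in control kidneys.

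The comparison of gout with healthy kidney asks which transcripts differ in the diseased organ. Among the genes with the largest rises, STC2, which encodes the secreted glycoprotein stanniocalcin 2, went from 3.68 ± 1.33 FPKM in control to 69.2 ± 19.9 in gout kidneys (SD, n = 6 and 5; log2 fold change 3.91, SE 0.27, limma adjusted p = 4.97e-06). IGFBP1, an insulin-like growth factor binding protein, rose from 3.10 ± 1.13 to 27.2 ± 11.4 FPKM (limma adjusted p = 0.000534). FKBP5, a co-chaperone of steroid receptors, rose from 61.7 ± 23.3 to 324 ± 40.8 FPKM in its more abundant row (log2 fold change 2.47, SE 0.30, limma adjusted p = 0.00145), and its second row rose as well. ZBTB16, a zinc finger transcription factor, rose from 1.11 ± 0.55 to 10.2 ± 5.49 FPKM. LAMA2, a laminin chain, rose from 3.83 ± 2.99 to 32.9 ± 14.1 FPKM, and AADAT, an aminotransferase of the kynurenine pathway, from 7.83 ± 2.63 to 68.4 ± 56.5 FPKM.

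ARMC12, CLPS and LHFPL5, which lie next to FKBP5 in the gene order of the RefSeq annotation of the Taihu goose genome assembly, were also among the largest rises, with log2 fold changes of 3.03, 3.90 and 2.64. CLPS, which encodes pancreatic colipase, reached 34.2 ± 26.4 FPKM in gout against 0.841 ± 0.396 in control kidneys, and LHFPL5 36.8 ± 42.0 against 3.19 ± 0.828 FPKM (18.3 in gout without replicate 4). CADM2, a cell adhesion molecule, and PRDX6, a peroxiredoxin, completed the named rises by size, at log2 fold changes of 2.20 and 1.78. A more abundant PRDX6 row, which stood for the gene in the antioxidant list, was not called. SOX4, a transcription factor of the tubular injury list, rose from 8.68 ± 2.72 to 20.6 ± 4.47 FPKM. In each of these named rows all 5 gout libraries lay above all 6 control libraries. The 13 named rows with rises stayed past the threshold in every limma setting in which they were tested, the removal of any single gosling and each scaling included; CADM2 and ZBTB16 did not reach the stricter filter.

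**Figure D2:**
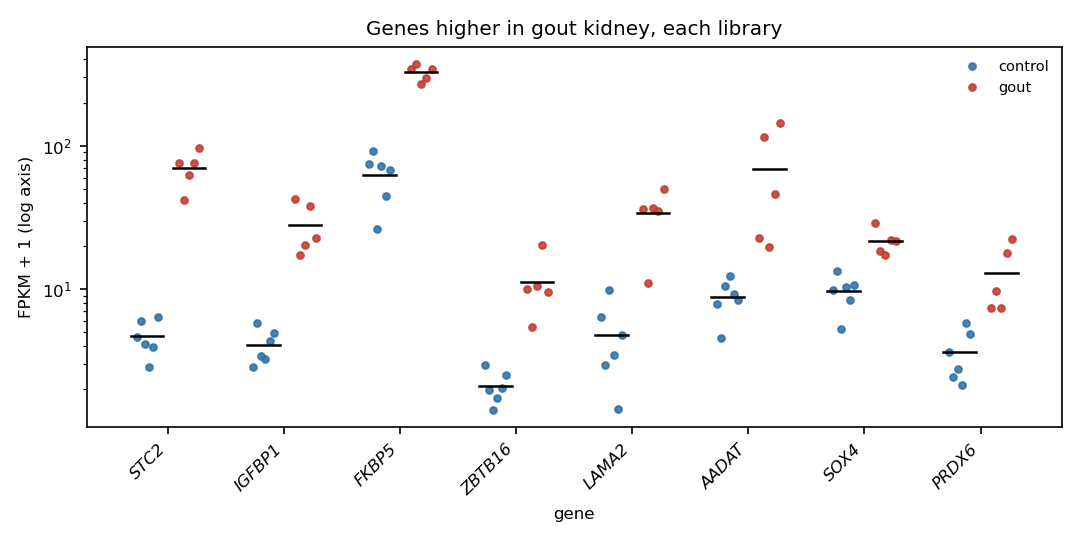
FPKM + 1 on a log axis in each library for 8 genes higher in gout kidney, control in blue and gout in red. Points are goslings and lines are group means. The gout libraries lay above the control libraries in each row shown, which the rule for the largest rises required of all but SOX4. The PRDX6 row shown is not the most abundant row of that gene. STC2 stood at 69.2 FPKM in gout and 3.68 in control.

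In total 856 of 12252 tested rows passed limma with Benjamini-Hochberg adjustment, 85 higher and 771 lower in gout. Of these, 576 changed at least 2-fold on the log2(FPKM + 1) scale, 70 higher and 506 lower. With single goslings left out the number of rows called ranged from 316 (without gout replicate 2) to 1466 (without gout replicate 5). The median log2 fold change of all tested rows was -0.29, and changes are to be read relative to it. After quantile normalization, which moved that median to 0.01, 471 rows passed, 226 higher and 245 lower, so that the share of rises went from 9.93% to 48.0%. Of the rows called, 325 were called the same way in both, 81 higher and 244 lower. Quantile normalization makes the distributions of the libraries equal. Upper quartile scaling gave 178 higher and 334 lower rows, 34.8% rises, and the TPM scale 141 higher and 571 lower, 19.8% rises. An exact rank-sum test of each row, two-sided, called 0 rows after adjustment, with 2182 rows at an unadjusted p under 0.05; its smallest possible p is 0.00433.

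Transcripts of lymphocytes and macrophages were lower in gout kidney. Of 26 lymphocyte markers tested, 17 fell, and of 18 macrophage markers 11 fell; no member of either list rose. Adjusted over the list alone, 20 lymphocyte and 15 macrophage members were lower. JCHAIN, the joining chain of secreted antibodies, went from 264 ± 169 to 26.0 ± 50.3 FPKM (log2 fold change -4.78, SE 0.84, limma adjusted p = 0.00796), CD8A, a T cell co-receptor, from 5.80 ± 2.81 to 0.736 ± 1.28, CD2, a T cell adhesion receptor, from 9.64 ± 3.28 to 1.81 ± 1.91, and CD79B, part of the B cell receptor, from 3.48 ± 1.47 to 0.282 ± 0.313 FPKM. Among macrophage members, MPEG1, a pore-forming protein of phagocytes, fell from 107 ± 67.9 to 20.4 ± 28.5 FPKM and CTSS, a lysosomal protease, from 81.4 ± 30.9 to 22.8 ± 7.16 FPKM. Without gout replicate 1 the gout means were 3.51 FPKM for JCHAIN, 0.162 for CD8A, 0.978 for CD2, 0.152 for CD79B and 7.74 for MPEG1. CXCR6, a chemokine receptor, was among the largest falls, at a log2 fold change of -2.06. After quantile normalization 9 lymphocyte and 3 macrophage members passed; LCP1 and LAPTM5 of the macrophage list were among those that did not (adjusted p = 0.0586 and 0.0510).

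The lymphocyte and macrophage lists were called lower by camera with a preset correlation of 0.01 (adjusted p = 1.24e-08 and 1.41e-06). Neither was called with an estimated correlation (adjusted p = 0.938 for each). Their medians relative to that of all rows were -0.82 and -1.40 on the log2 scale. In an exact two-sided permutation test of the list mean against the mean of all rows over all splits of the goslings, chosen after the data were seen, p was 0.00649 for lymphocytes and 0.00866 for macrophages, and 0.0641 for each after adjustment over the 37 lists. In that test the adrenal list, whose mean was higher in gout by 0.44 relative to all rows, had the same p-values as lymphocytes.

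**Figure D3:**
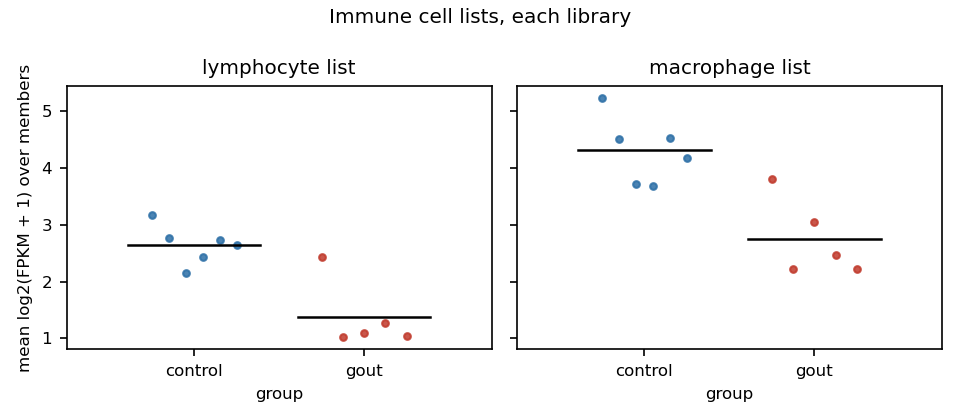
Mean log2(FPKM + 1) over the tested members of the lymphocyte and macrophage lists in each library, by group. Points are goslings and lines are group means; gout replicate 1, at 2.44 for lymphocytes and 3.80 for macrophages, lay inside the range of the control libraries, which was 2.15 to 3.16 and 3.68 to 5.23, and the other gout libraries lay below it.

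Part of the lysosomal genes were lower in gout. Of 33 members of the lysosome and autophagy list 11 fell, 22 did not pass and 0 rose, and 15 were lower when adjusted over the list alone. CTSZ fell from 107 ± 36.5 to 32.0 ± 19.8 FPKM, GLB1 from 24.9 ± 7.90 to 6.50 ± 1.89, and LAMP1, a lysosomal membrane protein, from 161 ± 38.8 to 63.3 ± 18.9 FPKM. Of 38 members of the fibrosis and extracellular matrix list 10 fell and LAMA2 rose; adjusted over the list alone 21 were lower and 1 higher. TNC, a matrix glycoprotein, fell from 11.2 ± 2.82 to 2.18 ± 0.815 FPKM, MMP2, a matrix metalloproteinase, from 19.9 ± 5.50 to 5.96 ± 2.09, and FBLN1 from 6.50 ± 2.07 to 1.71 ± 0.489 FPKM. In the cell cycle list 4 of 32 members fell, 13 when adjusted over the list alone, and in the heterophil list 2 of 8, LYZ and CXCR4; 4 of the 8 were lower over the list alone. After quantile normalization 6 lysosomal members were lower, 7 matrix members were lower and 1 higher, and 0 cell cycle and 0 heterophil members passed. The medians of the cell cycle and heterophil lists relative to all rows were -0.39 and -0.87 before and -0.39 and -0.89 after it.

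These 4 lists were called lower by camera with the preset correlation, at adjusted p = 0.000829 for lysosome and autophagy, 0.0107 for the matrix, 0.00224 for the cell cycle and 0.0455 for heterophils. None was called with an estimated correlation (adjusted p = 0.938 for each). After quantile normalization camera called all 4 with the preset correlation (adjusted p = 1.32e-05, 0.000472, 0.000480 and 0.0115) and none with an estimated one (adjusted p = 0.441, 0.441, 0.711 and 0.441). The heterophil call was lost without gout replicate 2, 4 or 5 and without control replicate 1, and the matrix and cell cycle calls without gout replicate 5 (adjusted p = 0.0658 and 0.13). The heterophil call was also lost with pseudocounts of 0.1 and 0.01, array weights, renamed LOC numbers and myeloid protein 1 as a covariate (adjusted p from 0.0506 to 0.189), the matrix call with the stricter filter (0.0925) and the cell cycle call with the covariate (0.14). The list tests thus called 6 of 37 lists lower and 0 higher, but 73 of 100 splits of the 11 libraries, the real one included, called at least 6, so the number of called lists does not stand apart from chance groupings.

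Transport and tubule markers were lower in part. Of 9 tested members of the urate and organic anion transport list 3 fell: SLC22A7, an organic anion transporter, from 46.0 ± 21.1 to 8.50 ± 5.42 FPKM (log2 fold change -2.40, SE 0.39, limma adjusted p = 0.00510), SLC22A2 from 15.3 ± 9.11 to 3.49 ± 3.90 and SLC16A9 from 14.8 ± 8.98 to 4.37 ± 2.63 FPKM. SLC22A7 alone of these passed after quantile normalization, and SLC22A2 and SLC16A9 lost the call when single goslings were left out; the gout mean of SLC22A2 was 2.01 FPKM without gout replicate 5. Of 23 proximal tubule members 6 fell, among them GATM, an enzyme of creatine synthesis (30.2 ± 33.7 to 0.438 ± 0.250 FPKM, with a control mean of 17.3 without control replicate 3), and SLC6A19, a neutral amino acid transporter (63.9 ± 53.2 to 7.39 ± 5.60 FPKM), and of 20 members of the distal list 3 fell: CALB1, a calcium-binding protein (51.2 ± 10.5 to 13.8 ± 5.92 FPKM), CLDN19, a tight junction protein, and SLC12A1, the salt transporter of the loop of Henle. The SLC12A1 call was lost after quantile normalization (adjusted p = 0.108) and without each of 5 single goslings, gout replicates 3 and 4 and control replicates 3, 5 and 6. Over each list alone 4, 7 and 7 members were lower. Camera did not call these lists (adjusted p = 0.0724, 0.125 and 0.117), and after quantile normalization it did with the preset correlation (0.0182, 0.0290 and 0.0380). With an estimated correlation none was called before (adjusted p = 0.938 for each) or after quantile normalization (adjusted p = 0.460, 0.785 and 0.785), and the exact permutation test of the list means after it gave adjusted p = 0.0999, 0.2 and 0.143.

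In the purine and uric acid synthesis list 0 of 20 members passed, also over the list alone, and PAICS had the smallest p (limma adjusted p = 0.0587). Camera with the preset correlation did not call the list (adjusted p = 0.656). Fry, which does not compare a list with other rows, called it lower (adjusted p = 0.0492). Its median log2 fold change was -0.45, against -0.29 for all tested rows. XDH, the xanthine dehydrogenase that makes uric acid, stood at 7.95 ± 1.23 FPKM in gout and 13.2 ± 6.42 in control kidneys (limma adjusted p = 0.246). The urate transporter SLC2A9 stood at 2.14 ± 1.71 and 3.91 ± 1.67 FPKM (adjusted p = 0.181). SPP1, osteopontin, stood at 1696 ± 1217 and 442 ± 157 FPKM (adjusted p = 0.155), and LRP2, the endocytic receptor megalin, at 2.68 ± 2.45 (1.65 without gout replicate 5) and 6.86 ± 5.23 (adjusted p = 0.149). ABCG2, ABCC4, IL6, TLR4 and ALB lay under the filter, and SLC22A6, HAVCR1, UMOD, IL1B and HBAA had no row under that symbol.

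**Figure D4:**
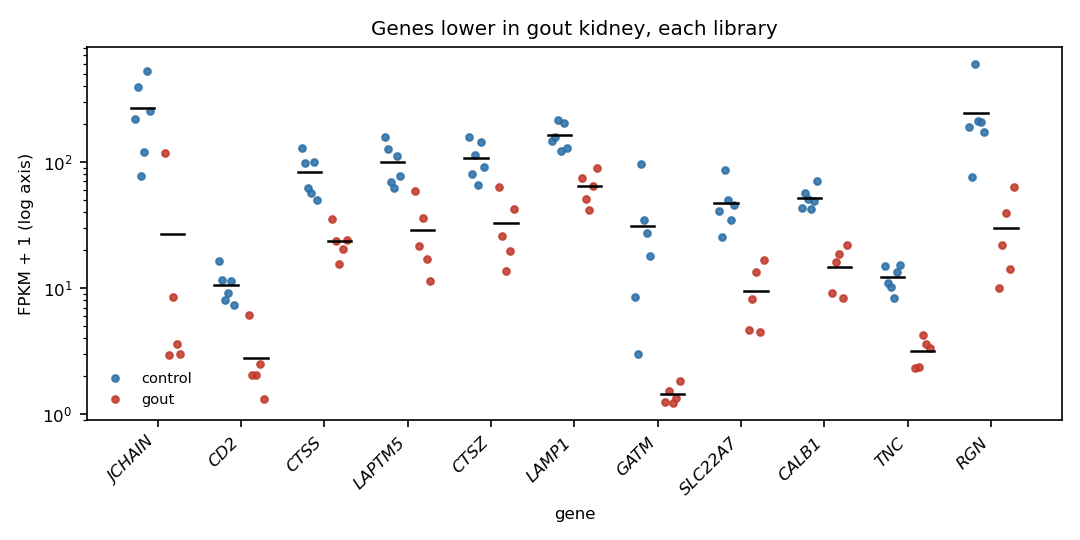
FPKM + 1 on a log axis in each library for 11 genes lower in gout kidney, control in blue and gout in red. Points are goslings and lines are group means; LAMP1 stood at 161 FPKM in control and 63.3 in gout kidneys, and the LAPTM5 call was lost after quantile normalization.

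The remaining falls by size were RGN, a calcium-binding protein of liver and kidney (241 ± 180 to 28.8 ± 21.9 FPKM), NELL2 (26.0 ± 6.17 to 3.73 ± 2.17), DNASE1L3, a secreted nuclease (17.4 ± 6.04 to 2.39 ± 2.44, with 1.36 in gout without gout replicate 1), SYNGR3, PSPH, an enzyme of serine synthesis, SEPP1, a selenium transport protein, CLEC3B and RHCG, an ammonia transporter. SEPP1 was not called after quantile normalization (adjusted p = 0.0557). In the calcium, phosphate and vitamin D list of 15, STC2 rose and 4 members fell, among them CALB1, SLC8A1 and CASR, and over the list alone 2 were higher and 4 lower. After quantile normalization CALB1 alone of the 4 was lower (adjusted p = 0.0797 for SLC8A1 and 0.0730 for CASR), and the SLC8A1 call was lost without gout replicate 2 and the CASR call without each of 6 single goslings. In the tubular injury list of 22, SOX4 rose and PLAU, a plasminogen activator, fell from 8.70 ± 2.46 to 2.03 ± 0.868 FPKM. Of the 69 named rows that fell, 35 stayed past the threshold without any single gosling and 36 under each of the 3 other scalings. Most of these falls entered as list members, where overlap of the groups was allowed, and all rises but SOX4 entered by size. The shares are therefore not to be compared with those of the rises.

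In the other lists few members passed. Members fell as follows and 0 rose: 3 of 21 in the cytokine list, 3 of 27 in the antioxidant list, 3 of 20 in the lipid and cholesterol list, 3 of 32 in the amino acid list, 2 of 13 in the complement list, 2 of 4 in the skeletal muscle list, and 1 each in the podocyte, interferon, erythrocyte and thrombocyte, TCA cycle, fatty acid oxidation, glycolysis and hypoxia, heat shock, drug metabolism and immediate early lists. In the endothelium, pattern recognition, adrenal, hepatocyte, smooth muscle, oxidative phosphorylation, p53 and apoptosis, unfolded protein, tight junction and ribosomal protein lists 0 members passed. After quantile normalization 2 antioxidant members were lower, 1 each in the cytokine, lipid and cholesterol, complement, fatty acid oxidation, glycolysis and hypoxia, heat shock and drug metabolism lists and 0 in the others, and 1 each was higher in the oxidative phosphorylation, p53 and apoptosis and ribosomal protein lists. Camera with the preset correlation called none of these lists on the deposited scale. After quantile normalization it called the ribosomal protein list higher (adjusted p = 0.0290) and the skeletal muscle and antioxidant lists lower (adjusted p = 0.04996 for each), and none of the 3 with an estimated correlation (adjusted p = 0.707, 0.441 and 0.441). The mitochondrial genome list had 0 members in the table.

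**Figure D5:**
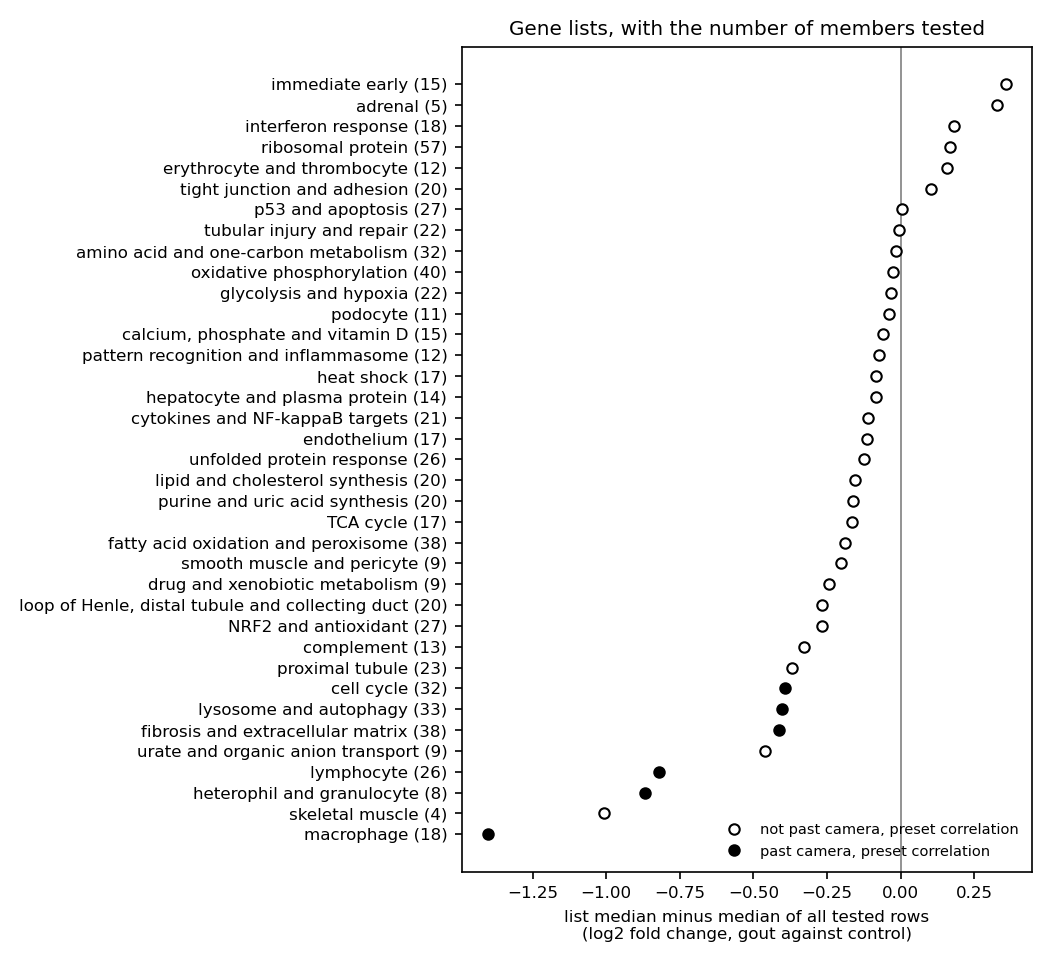
Median log2 fold change of each list minus that of all tested rows, gout against control, for the 37 tested lists with the number of members tested in parentheses. Filled points were called by camera with the preset correlation; none was called with an estimated correlation, and the macrophage list lay lowest at -1.40.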

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

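The tests of cell types and of the scaling as the whole of the fall were chosen after their results were seen, the latter once a first test of the scaling had left the matter open. Of 194 groups of named-gene values examined on the log2(FPKM + 1) scale, 8 held a library far from the rest by a criterion whose nominal level is about 1 in 20 groups by chance; 7 of them are given here. These were not spread evenly, since gout replicate 1 accounted for 5: it was high for JCHAIN (116 FPKM, next 7.47), CD8A (3.03, next 0.247), CXCR6 (2.10, next 0.437), MCM6 (9.06, next 5.02) and CDH2 (9.17, next 3.54). Gout replicate 2 was low for LAMA2 (10.1, next 34.1). Control replicate 3 was high for MUT (15.5, next 9.18).

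The lower lymphocyte and macrophage transcripts in gout kidney were weighed against 3 technical readings. Of 28 members called lower, 12 were still called after quantile normalization, which leaves open how much of the fall belongs to the authors' scaling. The median of all 44 members went from -1.29 (SD 0.86) to -0.97 (SD 0.86), so a scaling common to all rows does not account for all of it. The exact permutation p of their mean relative to all rows over the goslings was 0.00649 both times, unadjusted. That mean already takes out most of a library's scaling, and both lists were taken up because they fell, so the p-value adds little. In the same test each list alone had adjusted p = 0.0641, and 0.08 after quantile normalization. A lower share of every cell type beside tubule cells would move other types alike, but the immune median lay below those of endothelium, podocyte and smooth muscle markers. The gap was more than the SD of 0.86 over the immune members for endothelium (-0.89) and podocytes (-0.96). For smooth muscle it was less than that SD (-0.80, permutation p = 0.0197 over genes, which are not independent). The proximal and distal tubule lists were lower too, at medians of -0.66 and -0.55. Those of endothelium, podocytes and smooth muscle were -0.40, -0.33 and -0.49, so tubule markers were not kept relative to these types. With myeloid protein 1, a granulocyte precursor gene, as a covariate the median was -1.09 (SD 0.80) and 16 members were called lower. Most of the median fall thus remained beside this 1 gene. The gene stood at 3660 FPKM in gout replicate 3 and at 141 in control replicate 3. Whether it follows the share of such cells was not established, so their presence in control tissue stays open. All 5 gout libraries lay below the control mean, although gout replicate 1 (2.996) lay above control replicates 3 (2.788) and 4 (2.947), and a difference between gout and healthy kidney, for example in resident immune cells, may remain as a hypothesis.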

How the results depend on the processing

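Settings were planned before the data were examined except myeloid protein 1 as a covariate, renamed LOC numbers and quantile normalization without gout replicate 1 or with an estimated correlation. No named gene, and none of the 6 called lists, changed direction in any of them. The 856 calls and 576 calls of at least 2-fold became 471 and 279 after quantile normalization, 512 and 316 after upper quartile scaling, and 450 and 366 with the stricter filter, where 7083 rows were tested; the exact rank-sum test gave 0 and 0 (2182 rows at unadjusted p under 0.05) and 0 of the 82 called named rows. Quantile normalization kept 50 of the named calls, and without gout replicate 1 in addition it gave 52, with 365 calls of at least 2-fold. With single goslings left out the calls ranged from 316 to 1466, those of at least 2-fold from 275 to 860, the named calls from 49 to 85 and the called lists from 5 to 10; the count of calls fell by over 1.5 times without gout replicate 2 (316), 3 (461) or 4 (373) and control replicate 1 (456), 5 (319) or 6 (524), and rose by over 1.5 times without gout replicate 1 (1385) or 5 (1466). The 6 called lists became 12 after quantile normalization, 10 without a filter, 13 with fry and 0 with the estimated correlation, with or without quantile normalization. Beyond the smaller number of rows under the stricter filter, the cause was not tested. The replicate numbers name different goslings; deviations of same-numbered samples correlated at 0.241, -0.086, 0.018, -0.030 and 0.083, and a replicate block gave 671 calls, 572 of at least 2-fold, 7 lists and 68 named calls. Unknown depth limits what can be said of rows near 1 FPKM. For lists called in neither setting, camera's direction changed in some settings, with these medians relative to all rows. With a pseudocount of 0.01 this was -0.45 for hepatocyte. Without a filter this was -0.19 for oxidative phosphorylation and -0.27 for unfolded protein. With the stricter filter this was 0.17 for pattern recognition, -0.31 for hepatocyte, -0.0099 for oxidative phosphorylation and -0.12 for unfolded protein. After quantile normalization, with the preset or an estimated correlation, this was -0.12 for hepatocyte, -0.18 for smooth muscle, -0.045 for oxidative phosphorylation and -0.14 for unfolded protein. With upper quartile scaling this was -0.13 for hepatocyte, -0.18 for smooth muscle and -0.084 for unfolded protein. On the TPM scale this was -0.25 for hepatocyte, 0.038 for oxidative phosphorylation and -0.081 for unfolded protein. With array weights this was -0.068 for oxidative phosphorylation and -0.21 for unfolded protein. With the replicate block this was -0.16 for hepatocyte. With fry, which does not compare a list with other rows, this was -0.0048 for tubular injury, 0.18 for interferon, 0.16 for erythrocyte, -0.084 for hepatocyte, -0.20 for smooth muscle, -0.025 for oxidative phosphorylation, 0.0064 for p53 and apoptosis, -0.12 for unfolded protein, -0.058 for calcium, 0.10 for tight junction, 0.36 for immediate early and 0.17 for ribosomal protein. With myeloid protein 1 as a covariate this was -0.42 for hepatocyte, -0.12 for oxidative phosphorylation and -0.18 for unfolded protein. After quantile normalization without gout replicate 1 this was -0.043 for tubular injury, 0.079 for interferon, -0.22 for hepatocyte, -0.24 for unfolded protein and 0.067 for immediate early. With single goslings left out, the lists whose direction changed ranged from -0.28 to -0.024 for fatty acid oxidation, -0.22 to -0.023 for unfolded protein, -0.24 to 0.12 for amino acid, -0.45 to 0.040 for smooth muscle, -0.27 to -0.028 for cytokine, -0.28 to -0.007 for hepatocyte and -0.15 to 0.021 for oxidative phosphorylation.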

Other observations

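The pathway enrichment, the glucocorticoid list, the tests of transcripts running on from FKBP5 and of the scaling behind the excess of falls, and the genes named by LOC or assembler number were chosen after the data were seen. Of genes outside the fixed lists, a class II histocompatibility alpha chain (LOC106049922) went from 1335 ± 800 to 174 ± 147 FPKM (limma adjusted p = 0.00376) and an immunoglobulin mu heavy chain-like gene (LOC106049915) from 1011 ± 768 to 24.2 ± 47.1 FPKM (adjusted p = 0.00441). Without gout replicate 1 their gout means were 111 and 3.13 FPKM. A one-sided Fisher's exact test of the table's own pathway annotation over 6311 annotated tested rows and 255 pathways placed 15 of 30 rows of the intestinal IgA network among the rows lower in gout (2.17 by chance, adjusted p = 9.07e-08), 10 of 25 rows of cytochrome P450 drug metabolism (adjusted p = 0.000415) and 23 of 148 lysosome rows (adjusted p = 0.00918). After quantile normalization 6, 6 and 14 of them were lower (adjusted p = 0.00400, 0.00263 and 0.00262). Of 14 pathways called, 6 passed after it; those lost were protein digestion (adjusted p = 0.0508), retinol metabolism (0.0621), phagosome (0.0783), T cell receptor signaling (0.0790), globo-series glycosphingolipid synthesis (0.0841), natural killer cytotoxicity (0.189), neuroactive ligands (0.665) and NF-kappa B signaling (1). Of 11 rows of antigen processing and presentation 0 were called lower. Genes of a pathway are not independent in these tests. No pathway was called among the rises, but only 23 of the annotated rows were higher, against 457 lower, so this test could call little.

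An unnamed assembled row, MSTRG.5563, went from 296 ± 215 FPKM in control to 6028 ± 2992 in gout kidneys (log2 fold change 4.55, SE 0.47, limma adjusted p = 0.000534). Haemoglobin transcripts did not pass: the beta subunit (LOC106048580) stood at 3221 ± 2213 and 6117 ± 5207 FPKM (adjusted p = 0.596).

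FKBP5 and its neighbours ARMC12, CLPS and LHFPL5 formed a run of 4 neighbouring rises, and 0 of 100 random orders of 9226 placed genes, 40 of them higher, held such a run (longest 2). The run was seen before it was tested, and so few higher genes hardly ever form it in random order. The outcome was thus nearly fixed in advance and adds little. Transcripts running on from FKBP5 would fade with distance; LHFPL5 rose by 4.13 times as many FPKM as ARMC12, which lies nearer, but by 2.0 times without gout replicate 4, and its rise exceeded that of ARMC12 in 4 of 5 gout libraries, with a mean difference of 25.5 ± 40.7 FPKM (SD, n = 5). CLPS, also farther than ARMC12, rose by 4.10 times as many FPKM (4.78 without gout replicate 4) and by more in 5 of 5 gout libraries (difference 25.2 ± 27.2 FPKM), which goes against fading, but both differences lie within 1 SD and this stays open. Whether the whole neighbourhood changed cannot be told apart from a change of these genes: on the flanks TEAD3 had a log2 fold change of 0.93 after quantile normalization (adjusted p = 0.0272; 0.129 before), SRPK1 did not pass (adjusted p = 0.974), and TULP1 was under the filter. Strand is not given, so antisense or joined transcripts stay open.

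Whether the excess of falls over rises comes from the scaling cannot be told apart from a wide fall of transcripts: rises made up 34.8% of calls after upper quartile scaling and 19.8% on the TPM scale, and quantile normalization evens the balance by its construction. The 10 most abundant rows took 6.35 percentage points more of the FPKM in gout, which at equal totals would move the other rows by -0.12 on the log2 scale, against a median of -0.29, and so may account for part of the excess.

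FKBP5, ZBTB16 and IGFBP1 are known glucocorticoid-responsive genes, and a hypothesis is that glucocorticoid receptor activity was higher in the sick goslings. A list of 24 other known targets was written after the rows had been tested singly and before it was tested as a list. Some of its members, SGK1 among them, were also in the fixed lists. It had 15 tested members, with PDK4 alone passing (limma adjusted p = 0.0412). The list was higher by camera with the preset correlation (p = 0.00220; 0.0476 with an estimated correlation), and its mean relative to all rows differed between the groups (exact permutation p = 0.00216, the smallest the splits allow). Its median log2 fold change was 0.15, and members went both ways. RGCC stood at -0.74 (limma adjusted p = 0.0608), IL1R2 at -0.70 (0.155), SGK1 at -0.43 (0.439) and FOXO1 at -0.355 (0.190). PCK1 and ERRFI1 were slightly negative, and the other tested members were positive. Hormone levels were not measured here.

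Myeloid protein 1 (LOC106032697) ranged from 48.4 to 3945 FPKM over the libraries, and an antimicrobial peptide gene (LOC106038139) moved with it (Pearson r = 0.996, Spearman rho = 0.991, permutation p = 1e-05 for each, the smallest that 100000 resamples give; r = 0.996 without the 2 farthest libraries). Blood-forming tissue in some samples is a candidate explanation, but the relation with the cell cycle list did not decide it (r = 0.44, permutation p = 0.177, 0.177 adjusted over 2 relations; rho = 0.555, p = 0.0825; r = 0.641 without the 2 farthest libraries and 0.443 within the 6 controls).

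Of 100 splits of the goslings into 5 and 6, 1, the real one, gave 856 or more calls (highest other 328). The real one alone also gave 576 or more of at least 2-fold (highest other 243). Only part of the possible splits was drawn, so chance is unlikely to account for these counts, at about 1 in 100 and no finer. For the lists 73 of 100 splits called 6 or more, with 21 the highest other, so chance cannot be excluded for the number of lists.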
